A study of Mus musculus with 6 samples.

How the data were processed

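The 6 libraries come from RFP-positive sarcoma cells sorted out of tumours in mice, 3 carrying a scrambled hairpin (shSCR) and 3 a hairpin against Postn (shPostn). Per the labels, RNA was extracted with TRIzol and strand-specific poly(A) libraries were made and sequenced on the DNBSEQ platform by BGI. The deposited table holds estimated counts per Ensembl gene, which the authors made with Salmon against mm10 per the submitters' processing notes; the versions and the transcript annotation are not given in the sources used here. All 35727 genes had whole numbers in every library (0 values that were not whole), so rounding left them as they were, and 16265 genes had 0 counts in every library.

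Gene IDs were matched to GENCODE release M21 on GRCm38 (mm10): 35422 had a symbol and 35493 a position. Unmatched IDs held between 0.0536% and 0.0791% of each library's counts. Where IDs shared a symbol (38 symbols) the ID with the most reads took the plain symbol. Xist was not analysed here. Library totals lay between 19603269 and 20376554 counts, and the gene with the most counts took between 1.1340% and 1.7673% of a library. Differences of named genes with few counts in the lower group are also given as a count ratio with its exact interval.

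Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes passed filterByExpr with a minimum count of 10, TMM factors scaled the libraries, and a robust quasi-likelihood F-test compared shPostn with shSCR; p-values were adjusted by Benjamini-Hochberg over the 12819 genes tested, with a threshold of 0.05. There was 1 comparison, with no covariate, and log2 fold changes are shPostn minus shSCR. The SE of a log2 fold change is its size over the square root of F. CPM are counts scaled to TMM-normalised library sizes, and group means are given with their SD. The common biological coefficient of variation was 0.183. Postn was also compared by an exact 2-sided permutation test of its CPM values. Simulated data had the same size and spread and 200 changed genes of 12819. The test recovered 68% of 2-fold and 84% of 4-fold changes, with 6 false calls among 158 and 0 calls when no gene changed. Changes under 2-fold were not simulated, while the genes called in the data had a median absolute log2 fold change of 0.538. Recovery of such smaller changes was therefore not measured. Camera called the list that was moved and 0 unmoved ones. Genes were simulated independently of each other, so this cannot show how often camera calls unmoved lists whose genes vary together.

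Before the data were examined, 58 gene lists of pathways, matrix classes and cell types were written, as were the tests, the alternatives and the rule for named genes; the choices made later are named where they are used. Camera tested the 49 lists with at least 5 tested members, with a preset inter-gene correlation of 0.01 and adjustment over these lists, and an estimated correlation and fry were alternatives. Counts of members are given over all genes tested and adjusted over the list alone. The lists for adipocytes, B and plasma cells, dendritic and mast cells, erythroid cells, keratinocytes, myogenic cells, skeletal muscle, sex-specific genes and the design's own genes had fewer tested members and no list test; in them Postn and Des fell and no other gene passed. Adjusted over the list alone, Postn, 2 skeletal muscle genes and 1 keratinocyte gene fell. The rule named Postn, Ccne1 and Trp53. It also named the 10 largest changes in each direction among called genes whose libraries do not overlap and whose higher group has a mean of at least 1 CPM, without predicted and clone-named genes. For each list described it named the 2 called members with the largest change each way, or the 2 most abundant members if none was called. Further members of a list, Csf1, Ccl2 and the leukocyte, vessel, T cell and haemoglobin genes given per library were named after their values were seen. The results of 2 genes that the rule names are not reported here.

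Chromosome medians used genes with a mean above 4 CPM, bins of 10 Mb and bootstrap intervals at 95%. Ratios of low counts have 95% conditional Clopper-Pearson intervals. Reads carry no molecular identifiers, so intervals cover counting error only.

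The alternatives were relative log expression, upper quartile or no composition factors, no count filter or 1 CPM in 3 libraries, DESeq2 1.42.0 and limma-voom, a replicate block, the pan-leukocyte mean as a covariate, each library left out in turn, and for the lists an estimated correlation or fry. Taking each chromosome's median out of the model's offsets, and leaving out shPostn replicate 3 together with chromosomes 12 and 18, were added after seeing the data. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The labels give no batch, sequencing date or animal, so no batch was modelled.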

Results

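Gene expression was measured by RNA sequencing in 6 libraries of mouse undifferentiated pleomorphic sarcoma cells, sorted by their red fluorescence out of transplanted tumours. All came from 1 tumour cell line, made from mesenchymal stem cells of p53-deficient mice with a retroviral vector for cyclin E1 (Ccne1) and a red fluorescent protein. The line then received a viral hairpin RNA against Postn, the gene of the secreted matricellular protein periostin, or a scrambled hairpin. The 3 libraries with the Postn hairpin are called shPostn here and the 3 with the scrambled hairpin shSCR; sample titles call the former a knockout, while the protocol describes a hairpin. The deposited counts summed to between 19847860 and 20376554 per shSCR library and between 19603269 and 19931734 per shPostn library, with 15901 to 16666 genes detected in each. The labels do not say whether the libraries of a group came from separate tumours or mice. Each p therefore measures only the spread between these samples, which can be technical. The labels also name no further line per hairpin and no other hairpin against Postn. Even with separate tumours, a difference between the lines unrelated to periostin could not be told apart from an effect of reduced periostin.

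The comparison of shPostn with shSCR asks what sarcoma cells express differently inside tumours when their periostin is reduced, in a study concerned with periostin, sarcoma growth and tumour macrophages. Postn (ENSMUSG00000027750; GRCm38 chromosome 3, 54361109 to 54391037, plus strand) fell to 12.1% of its control level. It measured 4097, 3602 and 3225 CPM (counts scaled to the normalised library size) in the shSCR libraries and 217, 471 and 639 CPM in the shPostn libraries. The group means were 3641.5 ± 437 and 442 ± 212 CPM (SD, n = 3 each), a log2 fold change of −3.04 with a standard error (SE) of 0.41 and an edgeR adjusted p of 0.0125. An exact 2-sided permutation test of the CPM values gave p = 0.1, the smallest that 3 against 3 libraries allow. The Postn log2 fold change was −2.95 without shSCR replicate 1 (adjusted p = 0.0532) and −3.05 without shSCR replicate 2 (adjusted p = 0.0542). Ccne1, the transgene's cyclin, measured 17.0 ± 2.03 CPM in shSCR and 17.4 ± 2.16 CPM in shPostn (n = 3 each; log2 fold change 0.03, adjusted p = 0.898). Trp53, which encodes p53, measured 121 ± 1.98 and 118 ± 12.04 CPM (n = 3 each; log2 fold change −0.03, adjusted p = 0.868), and counts per gene cannot show whether these transcripts carry the deletion.

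Silencing of Postn went with the gain of a few genes that were close to absent in control cells and the loss of a larger number. Ptprg, a receptor-type protein tyrosine phosphatase (chromosome 14, 11553532 to 12242041), rose from 0.366 ± 0.240 CPM in shSCR to 55.2 ± 6.57 CPM in shPostn (SD, n = 3 each; log2 fold change 7.22, SE 0.32, adjusted p = 0.000727). Its 10 tested neighbours within 3 Mb had a median log2 fold change of 0.14, and their lowest adjusted p was 0.0775. Lepr, the leptin receptor and a marker of mesenchymal stem cells (chromosome 4, 101717404 to 101815352), rose from 2.45 ± 0.204 to 22.3 ± 9.25 CPM (log2 fold change 3.18, SE 0.32, adjusted p = 0.00502). Lama2, the laminin alpha 2 chain of basement membranes (chromosome 10, 26980036 to 27619758), fell from 30.9 ± 2.34 to 1.35 ± 0.590 CPM (log2 fold change −4.51, SE 0.26, adjusted p = 0.00121). The other 8 of the 10 highest rises were those of Mamld1 (log2 fold change 3.65), the potassium-chloride transporter gene Slc12a5 (3.48), the forkhead factor Foxl1 (3.32), the actin-binding transgelin gene Tagln (3.17), Dlk2 (3.11), Tspan2 (2.97), Hdgfl3 (2.86) and the neuronal deubiquitinase Uchl1 (2.82). The count ratio was 152 for Ptprg (3274 counts over the shPostn libraries against 22 over the shSCR libraries, 95% exact Clopper-Pearson interval 100 to 243), 13 for Mamld1 (127 against 10, 6.82 to 27.7) and 11.5 for Slc12a5 (146 against 13, 6.49 to 22). It was 10.5 for Foxl1 (62 against 6, 4.58 to 29.8) and 7.2 for Uchl1 (134 against 19, 4.43 to 12.3). With chromosome medians taken out the adjusted p was 0.0601 for Foxl1 and 0.0574 for Tspan2. The log2 medians taken out were small, −0.02 for Foxl1 (chromosome 8) and 0.02 for Tspan2 (chromosome 3). The log2 fold changes of both genes stayed close to those given above.

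The deepest losses, apart from Lama2, were in genes of low expression. Sgsm1 fell from 8.35 ± 1.01 to 0.135 ± 0.0778 CPM and Enpp5 from 5.78 ± 0.790 to 0.186 ± 0.0782 CPM (n = 3 each), with log2 fold changes of −5.89 (SE 0.37) and −4.91 (SE 0.35). Magea10, a member of the cancer-testis antigen family, had a log2 fold change of −5.10 (SE 0.57) and Lingo1 one of −4.53 (SE 0.70). The count ratio, shSCR over shPostn, was 62 for Sgsm1 (506 against 8, 31.2 to 144), 31.1 for Enpp5 (349 against 11, 17.2 to 62.9), 36 for Magea10 (294 against 8, 18 to 84.2) and 24.2 for Lingo1 (222 against 9, 12.5 to 53.6). Klf15, a Kruppel-like transcription factor, had 143 counts over the shSCR libraries against 2 over the shPostn libraries, a ratio of 70.1 (19.1 to 584). The ratio was 47.5 for Reep1 (97 counts against 2, 12.8 to 398), 46.6 for Tfcp2l1 (95 against 2, 12.5 to 390) and 34 for Cyp4f40 (104 against 3, 11.3 to 167). Intervals cover counting error only, since reads without molecular identifiers are not independent molecules. With 1 library left out, the adjusted p reached 0.142 for Foxl1 (without shSCR replicate 1), 0.105 for Tagln and 0.0886 for Uchl1 (both without shSCR replicate 3). Without shSCR replicate 2 it was 0.149 for Tspan2, 0.0627 for Cyp4f40 and 0.0663 for Lingo1. Of the 20 genes with the largest changes 13, Ptprg, Lepr and Lama2 among them, passed the test with any 1 library left out.

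**Figure D1:**
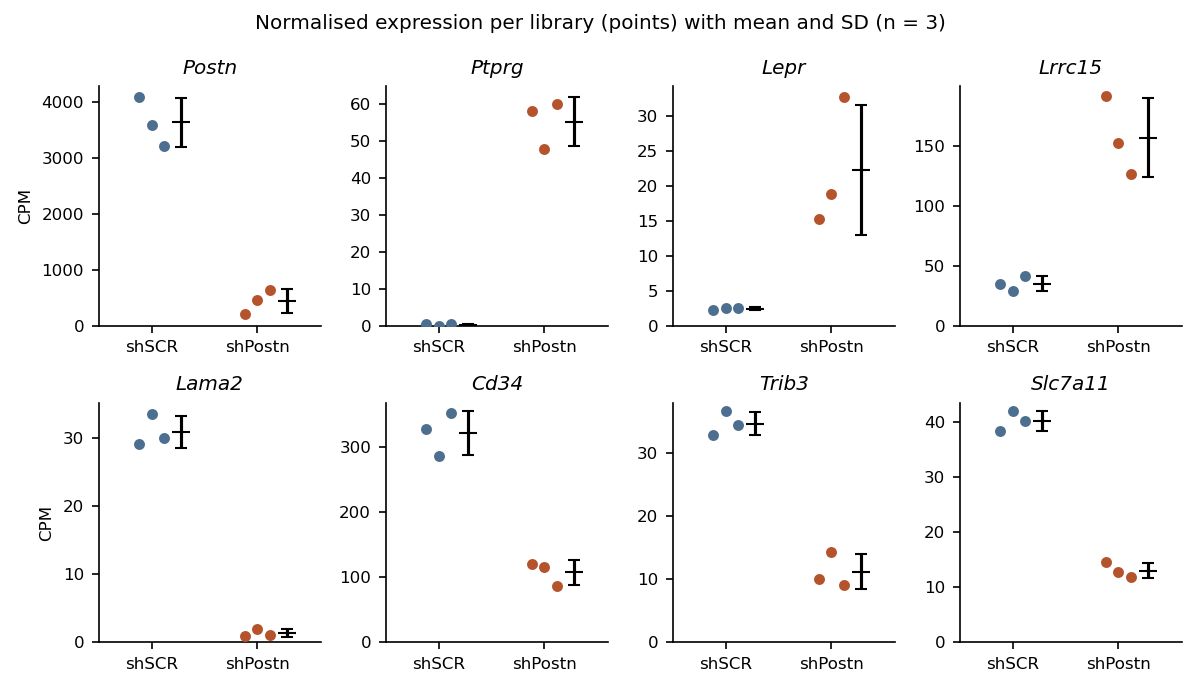
Normalised expression in CPM (vertical axes from 0) of 8 genes in each shSCR and shPostn library (points), with the mean (dash) and SD (bar) of each group of 3 libraries beside them. Postn, Lama2, Cd34, Trib3 and Slc7a11 lay lower in all 3 shPostn libraries than in any shSCR library, and Ptprg, Lepr and Lrrc15 lay higher.

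Of 12819 genes tested, 1300 (10.1%) changed, of which 591 rose and 709 fell in shPostn; 3458 had an unadjusted p under 0.05. The change was over 2-fold for 324 genes, with 123 higher and 201 lower, and over 8-fold for 7 higher and 43 lower. The libraries of both groups did not overlap at 4309 genes (33.6%), against 10% by chance for 3 against 3, and all 1300 changed genes were among them. The count of changed genes was 429 without shSCR replicate 1, 307 without shSCR replicate 2, 404 without shSCR replicate 3, 637 without shPostn replicate 2 and 2220 without shPostn replicate 3. Of these, 417, 306, 393, 586 and 1224 were among the 1300. shPostn replicate 3 stood apart on the 2nd principal component (33.4% of the variance, at 56.5 against −22.5 to 1.52 for the others), with high leukocyte genes as described further on. Without that library and without the genes of chromosomes 12 and 18, which shifted as a whole, 1552 genes changed, of which 668 rose and 884 fell. Of these 828 were among the 1300, of which 958 lay outside chromosomes 12 and 18.

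Targets of ATF4 and of the unfolded protein response, which cells induce when amino acids run short or misfolded protein builds up in the endoplasmic reticulum, were lower in shPostn. Of 29 measured members 12 fell, 1 rose and 16 did not pass the test; adjusted over the list alone, 15 fell and 2 rose. The list had a camera adjusted p of 7.41e-10, and an adjusted p = 0.178 with an estimated correlation. Slc7a11, the cystine importer, fell from 40.1 ± 1.80 to 13.0 ± 1.38 CPM (n = 3 each; log2 fold change −1.62, SE 0.10, adjusted p = 0.00114). Trib3, a pseudokinase induced by ATF4 and CHOP, fell from 34.7 ± 1.87 to 11.2 ± 2.74 CPM (log2 fold change −1.63, SE 0.17). Chac1, which degrades glutathione, had a log2 fold change of −1.32 (SE 0.18) and Sesn2, a stress-induced brake on mTORC1, one of −1.04 (SE 0.09). The serine and asparagine synthesis enzymes Psat1 (−0.68, SE 0.11), Phgdh (−0.52, SE 0.11) and Asns (−0.68, SE 0.13) also fell, as did the lipoprotein receptor Vldlr (−1.67, SE 0.26). The chaperone gene Dnajb9, on chromosome 12, rose (0.67, SE 0.12), with an adjusted p of 0.207 once chromosome medians were taken out. The list's call and those of Slc7a11, Trib3, Chac1 and Sesn2 held with any 1 library left out, while the adjusted p without shSCR replicate 2 was 0.0742 for Psat1, 0.123 for Phgdh, 0.107 for Asns, 0.0672 for Vldlr and 0.086 for Dnajb9.

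**Figure D2:**
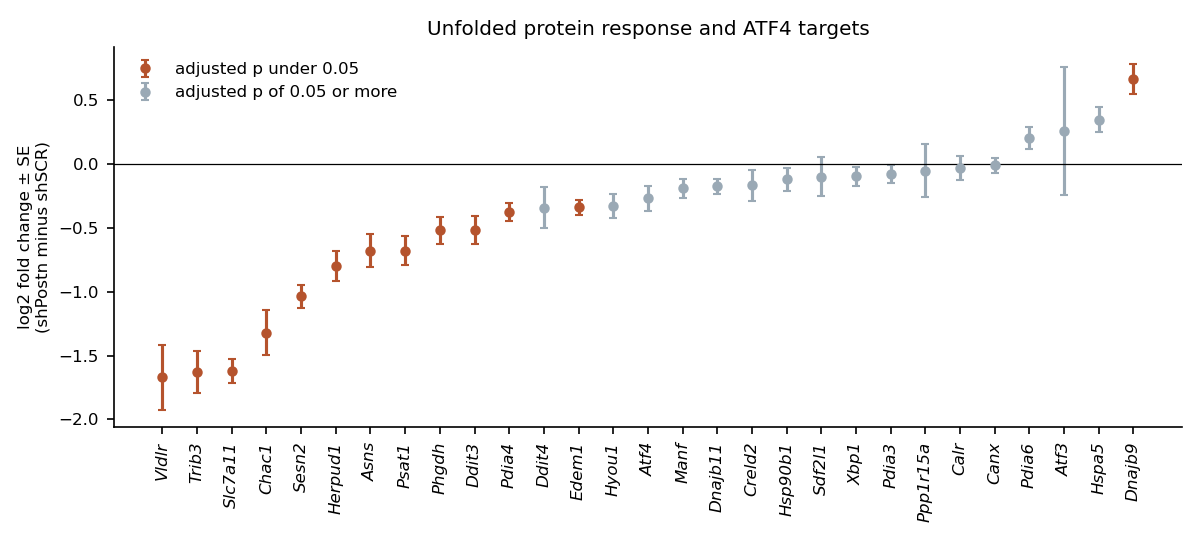
Log2 fold change (shPostn minus shSCR, n = 3 each) with its SE for the 29 measured genes of the unfolded protein response and ATF4 list, in order of size. Coloured points have an adjusted p under 0.05 over all genes tested, with 12 genes below 0 and Dnajb9 above.

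Basement membrane genes were lower in shPostn as a list with the preset correlation. Of 19 basement membrane genes 6 fell and 1 rose, the same counts as adjusted over the list alone (camera adjusted p = 0.000379; adjusted p = 0.746 with an estimated correlation). Beside Lama2, Col15a1 (log2 fold change −2.80, SE 0.67; 138 counts against 19, ratio 7.12, 4.39 to 12.2), the laminin gamma 1 chain gene Lamc1 (−0.54, SE 0.11) and the nidogen gene Nid1 (−0.38, SE 0.06) fell. The heparan sulfate proteoglycan genes Agrn (−0.68) and Hspg2 (−0.46), on chromosome 4, fell and the laminin beta 1 chain gene Lamb1 (0.63), on chromosome 12, rose; with chromosome medians taken out their adjusted p was 0.0607, 0.079 and 0.102. Among 17 fibrillar collagens Col27a1 alone rose, also adjusted over the list alone, from 115 ± 24.3 to 217 ± 27.4 CPM (n = 3 each; log2 fold change 0.92, SE 0.17; list adjusted p = 0.995). Of 21 genes of collagen processing 3 rose (3 and 1 that fell adjusted over the list alone), namely the prolyl hydroxylase subunit P4ha3 (1.19, SE 0.13), the procollagen protease Tll1 (2.31, SE 0.50) and the lysyl oxidase Loxl3 (0.90, SE 0.16), with a list adjusted p of 0.875. Chromosome medians taken out gave an adjusted p of 0.069 for Col15a1 and 0.0589 for Tll1, with log2 fold changes of −2.66 and 2.33. The fibrillar collagens had 1 that rose and 3 that fell without shPostn replicate 3, with a median of −0.26 against −0.39 for basement membrane genes, and collagen processing 3 and 3.

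Of 28 matrix proteases and inhibitors 3 rose and 3 fell (3 and 4 adjusted over the list alone; list adjusted p = 0.472). The counts were 3 and 8 without shPostn replicate 3, with a median log2 fold change of −0.44 and a list adjusted p of 0.0744. Timp3, a metalloproteinase inhibitor bound to the matrix, rose from 84.4 ± 3.40 to 223 ± 44.8 CPM (n = 3 each; log2 fold change 1.40, SE 0.15), and Mmp9 (1.13, SE 0.23) and the plasminogen activator gene Plat (0.44, SE 0.07) rose. Mmp15, a membrane-type metalloproteinase, fell from 6.59 ± 0.978 to 0.960 ± 0.278 CPM (log2 fold change −2.77, SE 0.27), and Mmp11 (−0.49, SE 0.11) and Mmp16 (−0.42, SE 0.09) fell. With chromosome medians taken out the adjusted p was 0.132 for Mmp16, 0.0505 for Mmp11, 0.0551 for Mmp9 and 0.057 for Thbs1. The log2 medians taken out were small for Mmp11 (0.01, chromosome 10) and for Mmp9 and Thbs1 (0.03, chromosome 2). Of 22 other matricellular genes, the family of Postn itself, 2 rose, namely thrombospondin 1, Thbs1 (0.91, SE 0.19), and fibulin 5, Fbln5 (0.89, SE 0.15), a chromosome 12 gene with an adjusted p of 0.107 once chromosome medians were taken out. Adjusted over the list alone 3 rose and 1 fell, with a list adjusted p of 0.323 that went with a negative median and a positive mean. Of 19 proteoglycan and elastic fibre genes Emilin1 (0.53) and Ltbp3 (0.45) rose (4 rose and 2 fell adjusted over the list alone; list adjusted p = 0.861). Matricellular genes had 3 that rose and 4 that fell without shPostn replicate 3, and proteoglycan and elastic fibre genes 5 and 1. In these matrix groups Lama2, Lamb1, P4ha3, Timp3 and Mmp15 passed the test with any 1 library left out. For the others the adjusted p without 1 library reached between 0.0611 for Emilin1 and 0.151 for Col15a1, both without shSCR replicate 2; Thbs1 and Mmp9 also lost their call without shPostn replicate 3.

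Genes of mesenchymal identity and of the response to TGF-beta changed in shPostn. Of 27 TGF-beta response genes 5 rose (9 and 1 that fell adjusted over the list alone; camera adjusted p = 0.000379; adjusted p = 0.684 with an estimated correlation). Lrrc15, a surface protein of TGF-beta-driven fibroblasts, rose from 35.2 ± 6.42 to 157 ± 33.0 CPM (n = 3 each; log2 fold change 2.15, SE 0.20, adjusted p = 0.00458). The TGF-beta inhibitor gene Skil (0.43, SE 0.06), Pmepa1 (0.64, SE 0.14), Tagln and Tgfb3 (0.62, SE 0.07) rose. Tgfb3 is on chromosome 12 and had an adjusted p of 0.117 once chromosome medians were taken out, where Pmepa1 had 0.0566. Leaving out shPostn replicate 3, the TGF-beta list had 5 that rose and 2 that fell, with a list adjusted p of 0.00905 (adjusted p = 0.815 with an estimated correlation). Of 17 mesenchymal stem cell markers 3 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0251; adjusted p = 0.746 with an estimated correlation). Nt5e, the CD73 ectonucleotidase, rose from 24.4 ± 1.78 to 64.9 ± 8.14 CPM (log2 fold change 1.41, SE 0.11, adjusted p = 0.00242), Alcam rose (0.66, SE 0.13), and the TGF-beta co-receptor endoglin, Eng, fell from 46.5 ± 6.45 to 9.08 ± 4.94 CPM (−2.35, SE 0.39). Of 15 fibroblast markers Cd34 fell from 321 ± 33.4 to 107 ± 18.7 CPM (log2 fold change −1.58, SE 0.14, adjusted p = 0.00343), Col15a1 fell and the actin-severing gelsolin gene Gsn rose (0.47, SE 0.07). In this list 3 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0251; adjusted p = 0.746 with an estimated correlation). The adjusted p of the mesenchymal list was 0.138 without shSCR replicate 2 and 0.0819 without shPostn replicate 3, and that of the fibroblast list 0.0642 without shPostn replicate 1. Lrrc15, Tgfb3, Lepr, Nt5e and Cd34 passed with any 1 library left out; without shSCR replicate 2 the adjusted p was 0.0553 for Skil, 0.123 for Pmepa1, 0.119 for Alcam, 0.0873 for Eng and 0.0578 for Gsn.

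Integrin genes, which encode receptors for matrix proteins including periostin, were higher as a list with the preset correlation. Directional fry did not call the list (adjusted p = 0.0902). Of 17 measured, 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0193; adjusted p = 0.746 with an estimated correlation). Itgb8, a subunit of an integrin that activates latent TGF-beta, rose from 7.24 ± 0.955 to 17.4 ± 0.555 CPM (n = 3 each; log2 fold change 1.26, SE 0.12), Itga3 rose (1.88, SE 0.27), Itga4 rose (2.07, SE 0.48) and Itga10 fell (−0.86, SE 0.18). Of 11 pericyte and smooth muscle markers Tagln and Myl9 (1.86, SE 0.34), parts of the contractile apparatus, rose and the filament gene Des fell (−3.49, SE 0.60), with 6 and 2 adjusted over the list alone and a list adjusted p of 0.0725. Of 14 regulators of epithelial-mesenchymal transition Foxc2 (1.56), Twist1 (0.54) and Snai1 (0.39) rose and Zeb1 fell (−0.44), with 4 and 1 adjusted over the list alone and a list adjusted p of 0.402. With chromosome medians taken out Twist1, on chromosome 12, had an adjusted p of 0.438 and Zeb1, on chromosome 18, a log2 fold change of 0.01 (adjusted p = 0.971), and the adjusted p was 0.066 for Itga4 and 0.0651 for Snai1. Without shPostn replicate 3 the adjusted p of the integrin list was 0.135, with 4 that rose and 2 that fell, and of the pericyte and smooth muscle markers none rose and 2 fell. Itgb8 passed with any 1 library left out; Tagln and Myl9 lost their call without shPostn replicate 3, among others. For Itga3, Itga4, Itga10, Tagln, Myl9, Des, Foxc2, Twist1, Snai1 and Zeb1 the adjusted p without 1 library reached between 0.0635 for Itga3, without shSCR replicate 3, and 0.172 for Itga4, without shSCR replicate 2.

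Among 22 signals that attract macrophages or sustain myeloid cells, Csf2, which encodes GM-CSF, fell from 3.91 ± 0.717 to 0.913 ± 0.275 CPM (n = 3 each; log2 fold change −2.09, SE 0.31, adjusted p = 0.00994). Mif fell from 306 ± 19.1 to 222 ± 30.5 CPM (−0.47, SE 0.11) and the chemokine gene Ccl5 rose from 3.93 ± 0.0253 to 8.07 ± 1.71 CPM (1.04, SE 0.18). The counts were the same adjusted over the list alone, and the list's adjusted p was 0.608. The most abundant member, Csf1, which encodes the macrophage growth factor M-CSF, measured 1015 and 1036.5 CPM (log2 fold change 0.03, adjusted p = 0.876), and the monocyte chemoattractant gene Ccl2 127 and 116 CPM (−0.13, adjusted p = 0.608). Of 16 checkpoint and phagocytosis signals Nt5e, the PD-L1 gene Cd274 (0.72, SE 0.14) and Anxa1 (0.34, SE 0.08) rose, also adjusted over the list alone, with a list adjusted p of 0.114. Of 35 genes of MHC class I presentation and the interferon gamma response, Cd274 and the peptide-loading gene Tapbp (0.64, SE 0.11) rose, also adjusted over the list alone (median log2 fold change 0.44; camera adjusted p = 0.00593; adjusted p = 0.882 with an estimated correlation). Of 36 type I interferon genes Ifi27 rose (0.30, SE 0.06) and none adjusted over the list alone, with a list adjusted p of 0.875; Ifi27 is on chromosome 12 and its log2 fold change was −0.08 (adjusted p = 0.472) once chromosome medians were taken out. Without 1 library the adjusted p reached 0.0585 for Csf2, 0.157 for Mif, 0.0855 for Ccl5, 0.0705 for Cd274, 0.182 for Anxa1, 0.0835 for Tapbp and 0.111 for Ifi27, each without shSCR replicate 2. The class I list had an adjusted p of 0.0672 without shPostn replicate 2. Of its 35 genes 8 rose and 3 fell without shPostn replicate 3, with a list adjusted p of 0.000509 (adjusted p = 0.947 with an estimated correlation). With that library left out the checkpoint list had 5 that rose and 1 that fell, the type I interferon list 1 and 3, and the macrophage-attracting list 2 and 3. With chromosome medians taken out the adjusted p was 0.0545 for Mif and 0.0766 for Anxa1.

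Leukocyte genes were high in 1 library, shPostn replicate 3, rather than in its group. Over 30 macrophage and monocyte markers the mean log2 of CPM plus 1 was 5.37 in that library and between 1.72 and 3.28 in the other 5, and 29 of the 30 were highest there. The values were 4.25 against 1.94 to 2.85 for 15 pan-leukocyte genes and 4.69 against 2.62 to 3.31 for 8 MHC class II genes. Lyz2, the macrophage lysozyme, measured 57.2 ± 29.2 CPM in shSCR and 142 ± 188 CPM in shPostn (n = 3 each), and Apoe 42.7 ± 22.1 and 189.6 ± 290 CPM. No gene of these lists passed the edgeR test over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05, and 0 were called by DESeq2 or limma-voom. The adjusted p of the lists was 0.279, 0.336 and 0.431. Without shPostn replicate 3 all 30 macrophage markers had a negative log2 fold change, with a median of −0.92 and a list adjusted p of 0.0223 (adjusted p = 0.947 with an estimated correlation), and none passed singly, while 3 had an unadjusted p under 0.05. Of 8 neutrophil markers Mmp9 rose (list adjusted p = 0.174), and no T and NK cell marker of 7 (0.851), nerve or glial marker of 6 (0.861) or lymphocyte- and neutrophil-attracting chemokine of 8 (0.402) passed; adjusted over the list alone the counts were the same. At an unadjusted p under 0.05 in edgeR these 3 lists held 0, 2 and 0 genes, with 0, 2 and 0 called by DESeq2 and none by limma-voom. Of 7 endothelial markers Eng fell (2 fell adjusted over the list alone; camera adjusted p = 0.0282; adjusted p = 0.746 with an estimated correlation), and the list's adjusted p was 0.0675 without shPostn replicate 1. When shPostn replicate 3 was left out 3 endothelial markers fell, with a list adjusted p of 0.000154 (adjusted p = 0.815 with an estimated correlation), and 1 nerve or glial marker rose.

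**Figure D3:**
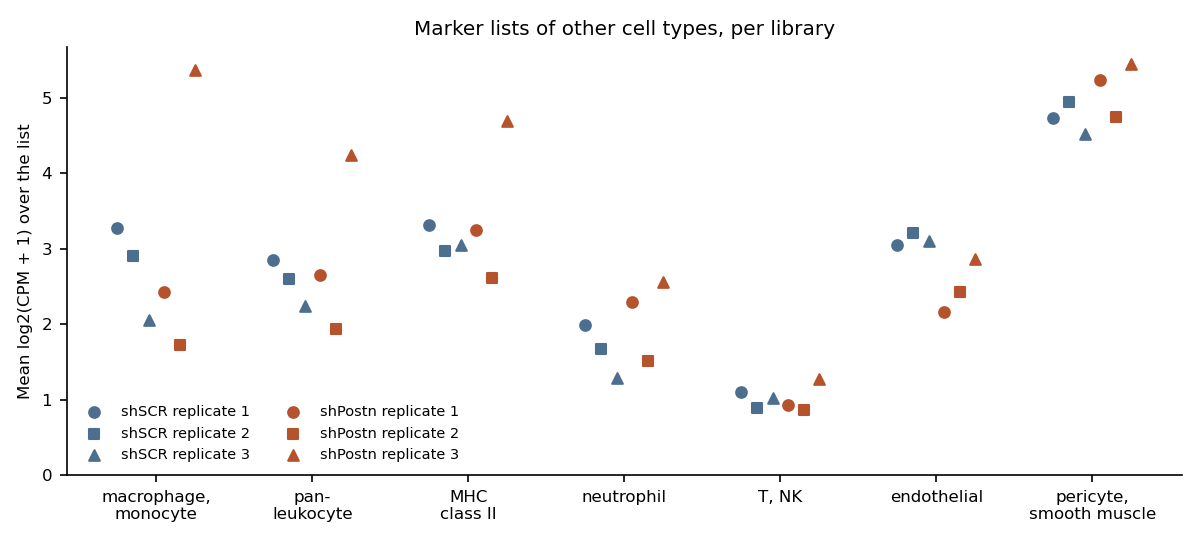
Mean log2 of CPM plus 1 over the tested genes of 7 marker lists (horizontal axis) in each of the 6 libraries (colour for group, shape for replicate). shPostn replicate 3 lay at 5.37 on the macrophage list, against 1.72 to 3.28 in the other libraries.

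Single genes of cell division and ribosome production changed, in a comparison where 10.1% of all genes tested did. Of 37 genes of G2/M and mitosis the kinesin gene Kif20a (log2 fold change −0.57, SE 0.07), Cdc25c (−0.53), Cdca8 (−0.49) and Kif2c (−0.43) fell, also adjusted over the list alone (camera adjusted p = 0.000762; adjusted p = 0.882 with an estimated correlation). Kif20a and Cdc25c are on chromosome 18 and Cdca8 and Kif2c on chromosome 4; with chromosome medians taken out their adjusted p was 0.337, 0.657, 0.0596 and 0.0834. Of 30 MYC and ribosome biogenesis genes, the rRNA transcription factor gene Tcof1, on chromosome 18 (−0.87, SE 0.08, adjusted p = 0.00312), and Nop16 (−0.75, SE 0.13) fell, also adjusted over the list alone (camera adjusted p = 0.0181; adjusted p = 0.914 with an estimated correlation). Without shPostn replicate 3, the library with high leukocyte genes, the adjusted p was 0.118 for the G2/M list and 0.478 for the MYC list. Of 34 genes of G1/S and DNA replication Rrm2, on chromosome 12, rose (0.55; adjusted p = 0.518 once chromosome medians were taken out) and none adjusted over the list alone, with a list adjusted p of 0.286. Of 13 cell cycle inhibitors and cyclins D, p27, Cdkn1b (0.29, SE 0.07), rose and Ccnd3 (−0.53, SE 0.10), Cdkn2d (−0.37, SE 0.08) and Cdkn2c (−0.32, SE 0.07) fell, with 2 and 3 adjusted over the list alone and a list adjusted p of 0.41. Directional fry called this list as lower (adjusted p = 0.0195). Cdkn2c had an adjusted p of 0.208 once chromosome medians were taken out, and without shPostn replicate 3 the list had 2 that rose and 4 that fell. Kif20a and Tcof1 passed with any 1 library left out. For the other genes here the adjusted p without 1 library reached between 0.0592 for Cdca8, without shSCR replicate 1, and 0.146 for Cdkn2c, without shSCR replicate 2.

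Of the metabolic groups, hypoxia response genes were lower as a list with the preset correlation (median log2 fold change −0.28, camera adjusted p = 0.0355). With an estimated correlation the hypoxia list's adjusted p was 0.914. Of 24 measured, 1 passed, the stanniocalcin gene Stc2, which fell from 11.4 ± 1.33 to 4.43 ± 1.04 CPM (n = 3 each; log2 fold change −1.36, SE 0.20), also adjusted over the list alone. Without shPostn replicate 3 all 24 were negative and 14 fell, with a median of −0.67 and a list adjusted p of 4.72e-09 (adjusted p = 0.815 with an estimated correlation). The hypoxia list's adjusted p was 0.306 without shPostn replicate 2 and was also over the threshold without shSCR replicate 1 or shPostn replicate 1. Cholesterol synthesis genes were higher as a list with the preset correlation (median 0.37, camera adjusted p = 0.0251, and 0.914 with an estimated correlation). None of 25 passed the edgeR test singly or adjusted over the list alone, 3 had an unadjusted p under 0.05, and DESeq2 and limma-voom called none. The sterol regulator Srebf2 measured 429 ± 36.6 and 467 ± 47.6 CPM. The cholesterol list's adjusted p was 0.278 without shPostn replicate 1 and also over the threshold without shSCR replicate 3. Without shPostn replicate 3, 5 of its genes rose, with a median of 0.54 and a list adjusted p of 8.79e-05 (adjusted p = 0.947 with an estimated correlation). Of 34 nuclear genes of oxidative phosphorylation Ndufa2 (−0.81, SE 0.08) and Atp5a1 (−0.54, SE 0.07), both on chromosome 18, and Sdhc (−0.47, SE 0.08) fell, also adjusted over the list alone, with a list adjusted p of 0.0725. The adjusted p once chromosome medians were taken out was 0.0457 for Ndufa2 and 0.511 for Atp5a1, and without shSCR replicate 2 it was 0.0579 for Stc2 and 0.0725 for Sdhc. Of 22 glycolysis genes Pfkfb4 (0.67, SE 0.09) and Pfkm (0.32, SE 0.08) rose (1 adjusted over the list alone; list adjusted p = 0.731). Of 35 ribosomal protein genes Rps14 (−0.53), on chromosome 18, and Rps6 (−0.31), on chromosome 4, fell (1 adjusted over the list alone; list adjusted p = 0.0697). With chromosome medians taken out the adjusted p was 0.634 for Rps14, 0.221 for Rps6 and 0.0725 for Pfkm. The glycolysis list had 1 that rose and 3 that fell without shPostn replicate 3. Pfkfb4 passed with any 1 library left out, and the adjusted p without shSCR replicate 3 was 0.163 for Pfkm, 0.0685 for Rps14 and 0.145 for Rps6.

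Every part of chromosome 12 was expressed more, and every part of chromosome 18 less, in shPostn. Over 375 genes of chromosome 12 above 4 CPM the median log2 fold change was 0.39 (95% interval 0.37 to 0.41), 1.31-fold, with 91.5% of genes and 12 of 12 bins of 10 Mb above 0. Over 281 genes of chromosome 18 it was −0.45 (−0.47 to −0.42), 0.733-fold, with 91.1% of genes and 9 of 9 bins below 0. Chromosome 4 had a median of −0.14, with −0.17 past 60 Mb and −0.07 before it, and 15 of its 16 bins below 0. Its medians in the 3 shPostn libraries, −0.17, −0.18 and −0.09, lay under every shSCR library. Of its 780 tested genes 132 changed (16.9%, against 9.75% elsewhere; Fisher's exact adjusted p = 1.52e-08), of which 114 fell and 18 rose. The medians of the other chromosomes lay between −0.06 and 0.08. Relative to the shSCR mean, the medians of the 3 shPostn libraries were 0.50, 0.40 and 0.25 for chromosome 12 and −0.44, −0.46 and −0.44 for chromosome 18, with the shSCR libraries between −0.04 and 0.03. Chromosomes 12 and 18 held 342 of the 1300 changed genes (26.3%) and 811 (6.33%) of the tested ones; 167 genes of chromosome 12 rose and 8 fell, and 166 of chromosome 18 fell and 1 rose. With each chromosome's median taken out 652 genes changed, 617 of them among the 1300.

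**Figure D4:**
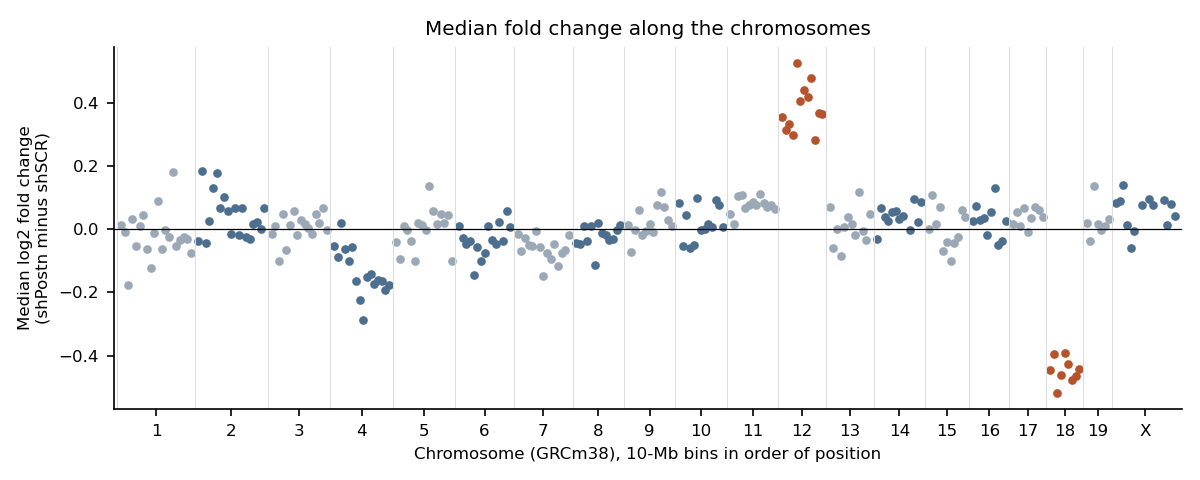
Median log2 fold change (shPostn minus shSCR, vertical axis) of genes above 4 CPM in bins of 10 Mb along the GRCm38 chromosomes (horizontal axis), each point a bin. All 12 bins of chromosome 12 lay between 0.28 and 0.52 and all 9 bins of chromosome 18 between −0.52 and −0.39 (both coloured).

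Lists that read RNA quality and handling held no changed gene. None of 13 mitochondrially encoded genes (list adjusted p = 0.769), 19 replication-dependent histone genes (0.882) or 25 immediate early genes that cell dissociation induces (0.179) passed the edgeR test, also adjusted over the list alone. Their counts at an unadjusted p under 0.05 were 2, 1 and 1, with 2, 0 and 1 called by DESeq2 and 0, 0 and 1 by limma-voom.

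Camera called 12 of 49 lists, 5 higher and 7 lower, and 17 had an unadjusted p under 0.05. None was called with an estimated correlation, where the lowest adjusted p was 0.178 and 2 lists had an unadjusted p under 0.05, and each of the 9 other ways to split the 6 libraries into 3 and 3 gave 14 to 22 called lists with the preset correlation. By fry's directional test 3 lists passed, namely the unfolded protein response list (adjusted p = 0.00588), the cell cycle inhibitors and cyclins D (0.0195) and the p53 targets (0.0222).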

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

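Taking chromosome medians out, and leaving out shPostn replicate 3 with chromosomes 12 and 18, were chosen only after the data were seen. The 1300 changed genes, 591 higher and 709 lower, stayed within 1.5 times under 3 other scalings, 2 other filters and limma-voom, while DESeq2 called 1937 genes, 943 of them higher. The combined setting, without shPostn replicate 3 and chromosomes 12 and 18, gave 1552 genes, 828 of them among the 1300. As 958 of the 1300 lay outside chromosomes 12 and 18, the 1552 compares with 958. A replicate block gave 735 genes, 321 higher and 414 lower, with a Postn log2 fold change of −3.159 (adjusted p = 0.0592). The block uses up degrees of freedom, and the replicate numbers do not pair the libraries (correlations of deviations −0.0719, −0.126 and −0.442). The pan-leukocyte covariate gave 2109, 963 higher and 1146 lower, and the chromosome medians taken out gave 652, 294 higher and 358 lower. What sets these counts apart was not tested. Genes of chromosomes with small medians also lost their call, so the 652 does not measure the chromosome shift alone.

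With 1 library left out the changed genes numbered 307 to 2220, 118 to 1028 higher and 189 to 1192 lower, with fewer samples in each fit. The Postn log2 fold change lay between −3.403 and −2.714 and missed the threshold at −2.949 (without shSCR replicate 1) and −3.05 (without shSCR replicate 2). Over the other settings its adjusted p ranged from 2.35e-11 (DESeq2) to 0.0592 (replicate block).

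Of 120 called named genes 32 passed with any 1 library left out, 28 of them also with chromosome medians taken out; 88 lost their call without some library, 87 of them without shSCR replicate 2. Relative log expression ended the call of 0, as did the stricter filter and DESeq2 among the genes they tested. The stricter filter tested 125 of the 130 named genes, called or not, without Foxl1, Tfcp2l1 and Cyp4f40 among others, and DESeq2 tested 129. Upper quartile ended the call of 3, library totals of 1, no filter of 9, limma-voom of 8, the covariate of 2 and the replicate block of 44. Chromosome medians taken out ended the call of 35 genes that kept their sign and 2 that did not. These were Zeb1 and Ifi27: Zeb1 log2 fold change was 0.009063 and Ifi27 log2 fold change −0.08314, with an adjusted p of 0.971 and 0.472. Among the 35 are genes of chromosomes with small medians, such as Foxl1, Tspan2, Tll1, Itga4 and Mif. For such genes a lost call does not show that position explains the change.

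Against 12 of 49 lists called as reported, an estimated correlation called 0, fry 3 by its directional test and 34 in either direction, and 1 library left out 10 to 17. Of the 12 lists directional fry ended the call of 11 and fry in either direction of 2. The list of macrophage and monocyte markers turned to lower and passed the threshold without shPostn replicate 3 (adjusted p = 0.0223) and in the combined setting (0.0153), since that library holds its high values. Without shPostn replicate 2 it passed in the other direction, higher, with 0.000512, and the highest adjusted p with 1 library left out was 0.589, without shSCR replicate 3. Over all settings it was 0.97, with an estimated correlation. Unrounded counts were not run, since every deposited value is whole. Depth limits genes with few counts, as the intervals of their ratios show.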

Other observations

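All tests on chromosome copies, on leukocytes carried through the sort and on a mislabelled library were chosen only after the result they measure was seen, as were the settings with chromosome medians taken out and with shPostn replicate 3 and chromosomes 12 and 18 left out.

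Genes of skeletal differentiation and of WNT signalling fell or rose singly in shPostn. Of 8 osteoblast genes the transcription factor Sp7 (log2 fold change −2.44, SE 0.44; 46 counts against 8, ratio 5.64 with a 95% interval of 2.63 to 13.8) and the growth factor Bmp4, from 20.9 ± 2.77 to 7.87 ± 2.30 CPM (n = 3 each; −1.41, SE 0.23), fell, with 1 more that rose adjusted over the list alone (list adjusted p = 0.453). The chondrogenic factor Sox5 rose (1.96, SE 0.28), 1 of 7 cartilage genes, also adjusted over the list alone (list adjusted p = 0.282). The tendon factor Mkx rose (1.07, SE 0.21), 1 of 9 tendon genes and 2 adjusted over the list alone (list adjusted p = 0.248). Of 15 WNT targets and modulators the feedback inhibitors Nkd1 (−2.56, SE 0.28) and Notum (−2.32, SE 0.41) fell (3 fell and 1 rose adjusted over the list alone; list adjusted p = 0.737). Nkd1 passed with any 1 library left out. The adjusted p without shSCR replicate 2 was 0.0709 for Bmp4, 0.0896 for Sp7, 0.0566 for Sox5 and 0.0942 for Mkx. Without shSCR replicate 3 it was 0.0699 for Notum. Of 23 YAP and TAZ targets Nt5e and Rbms3 (0.51) rose, also adjusted over the list alone (list adjusted p = 0.677). Rbms3 had an adjusted p of 0.103 without shSCR replicate 2. When shPostn replicate 3 was left out the YAP and TAZ list had 2 that rose and 4 that fell, the osteoblast list 1 and 2, the WNT list 1 and 2, and the tendon list 3 that rose. For WNT (median 0.17, mean −0.23, test lower), p53 targets (0.02, −0.18, lower), apoptosis regulators (0.05, −0.01, higher), matricellular proteins (−0.09, 0.21, higher) and collagen processing (−0.09, −0.01, higher) the median, the mean and the list test differ in sign.

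Cytokine receptors, growth factors and survival genes also changed singly. Of 19 genes of the STAT3 and IL-6 family response the oncostatin M receptor gene Osmr, from 22.7 ± 0.691 to 10.1 ± 3.61 CPM (n = 3 each; log2 fold change −1.17, SE 0.23), and Il6st (−0.40, SE 0.07) fell, also adjusted over the list alone (list adjusted p = 0.394). Of 23 NF-kB and TNF response genes Tnip1 fell (−0.33), also adjusted over the list alone (list adjusted p = 0.745). Of 25 growth factors and receptors Met rose (0.47, SE 0.10) and Igf2 (−3.19, SE 0.70; 225 counts against 24, ratio 9.19 with a 95% interval of 6.02 to 14.6) and Igfbp4 (−0.50, SE 0.12) fell, also adjusted over the list alone (list adjusted p = 0.323). Of 24 angiogenic factors Thbs1, Efna1 (0.47), Angptl4 (0.45), Angptl2 (0.42) and Pdgfc (0.36) rose, also adjusted over the list alone (list adjusted p = 0.0725). Bcl2 (0.63), Casp8 (0.37) and Xiap (0.25) rose among 24 apoptosis regulators, with 4 up and 4 down adjusted over the list alone (list adjusted p = 0.843). Sesn2 fell among 21 p53 targets, also adjusted over the list alone (list adjusted p = 0.279). The glutathione transferase gene Gsta4 rose (1.69, SE 0.41) and Slc7a11 fell among 22 NRF2 targets, also adjusted over the list alone (list adjusted p = 0.932). Sesn2 and Slc7a11 passed with any 1 library left out. Without shSCR replicate 2 the adjusted p was 0.119 for Osmr, 0.086 for Il6st, 0.109 for Tnip1, 0.142 for Igf2, 0.158 for Igfbp4, 0.14 for Thbs1 and 0.0876 for Efna1. It was 0.147 for Angptl4, 0.098 for Angptl2, 0.112 for Pdgfc, 0.165 for Casp8 and 0.151 for Xiap there. It was 0.106 for Met and 0.135 for Gsta4 without shSCR replicate 3, and 0.146 for Bcl2 without shSCR replicate 1. With chromosome medians taken out Bcl2 (0.0585), Igf2 (0.0565), Xiap (0.118), Gsta4 (0.0651), Angptl4 (0.0699) and Thbs1 (0.057) missed the threshold. The growth factor list passed as lower without shPostn replicate 3 (adjusted p = 0.0223; 0.815 with an estimated correlation), with 2 genes that rose and 8 that fell. There 4 fell in the STAT3 list, 3 rose and 1 fell in the NF-kB list and in the NRF2 list, 1 rose and 4 fell among p53 targets, 5 and 3 among angiogenic factors, and 2 and 2 among apoptosis regulators.

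In 6 of 6 chromosome and library pairs the medians of chromosomes 12 and 18 lay beyond all shSCR libraries, with every bin moving together. A changed number of copies predicts this. Chromosomes 7 and 11 also met this criterion, with medians of −0.06 and 0.08. Chromosomes 4, 17 and X, with medians of −0.14, 0.03 and 0.06, passed only the test's bar of 80% of bins (15 of 16, 8 of 9 and 11 of 13). The shift was larger on 12 and 18, where 91.5% and 91.1% of genes moved with the median, against 58.2% to 77% on the others named. Of the tested genes of 12 and 18, 37.4% and 48.7% changed, against 6.24% to 16.9%. GC content, length and expression level are argued against as the cause, since matched genes of other chromosomes had medians of 0.01 and 0.02, at least 0.375 (log2) away from the chromosomes' own. Leukocyte RNA in shPostn replicate 3 is argued against too, since without that library the medians kept at least 0.983 of their size. A candidate explanation is a gain of chromosome 12 and a loss of chromosome 18 in the shPostn line, and whether chromosome 4 differs in a part of the cells stays open. Whether such a change arose by chance when the line was split or went with the loss of periostin cannot be settled, since the labels name no second line per hairpin; DNA copy number was not analysed here.

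Leukocyte genes stood high in shPostn replicate 3, and a candidate explanation is macrophages or their RNA carried through the sort for red fluorescence, which would remove host cells that hold no tumour cell material. The macrophage, pan-leukocyte and MHC class II lists rose together there, by a median log2 ratio of 2.08 or more to the other shPostn libraries, with Csf1r at 73.2 CPM against 4.45 to 15.7 and Adgre1 at 31.5 against 1.06 to 5.51. A mislabelled library is argued against by its Postn level and by its chromosome 12 minus chromosome 18 difference of 0.695, on the shPostn side of every shSCR library. The macrophage list's ratio stood 3.1 (log2) above the lowest of the endothelial, pericyte and T cell lists, that of T cells. This gap cannot exclude host cells of every type alike. Cd3d, Cd3e and Cd3g lay at 0.355 CPM or less in every library, with Cd3e at 0.0999 CPM in shPostn replicate 3. Pdgfrb of the pericyte list measured 506 to 956 CPM in every library, so a small share of pericytes would not show. The endothelial list rose less than the macrophage list (median log2 ratio 0.569 against 3.41). Pecam1 (3.15 against 0.41 to 1.12), Kdr (0.699 against 0.0492 to 0.244) and 3 of 3 erythroid genes (median log2 ratio 2.98) were also highest in shPostn replicate 3. Cdh5 was at 2.1 there, against 0.359 and 0.607 in the other shPostn libraries and 1.23, 2.44 and 3.3 in the shSCR libraries. Of the 7 tested endothelial markers 1 was highest there. Their mean log2 of CPM plus 1 was 2.87 there, under the shSCR libraries (3.05 to 3.21) and over the other shPostn libraries (2.16 and 2.42). Blood or a smaller share of vessel cells stays open. Of the 30 macrophage markers 23 reached 1 CPM in all other libraries and 0 stand in another list, and a change of the sarcoma cells' own expression, or more macrophages in that tumour, stays open.

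Leukocyte RNA is argued against as the cause of the lower expression of ATF4 and unfolded protein response targets, since without shPostn replicate 3 the list's median kept 0.789 of its size, though the list's adjusted p there was 0.411 with an estimated correlation. Position on the shifted chromosomes predicts that camera stops calling the list once chromosome medians are taken out. With the preset correlation camera still called it there (adjusted p = 2.54e-14). The estimated correlation was not run in that setting, so this covers the preset call only. The edgeR adjusted p there was 0.00106 for Slc7a11, 0.00564 for Trib3, 0.0124 for Chac1 and 0.00564 for Sesn2. GC content, length and expression level are argued against by a ratio of −0.0558 between the median of matched genes and the list's own. The list's camera p was 1.51e-11 for the real split and 8.47e-05 or more for the other 9. Of these, 5 also called the list (adjusted p 0.000415 to 0.0362). Each side of those splits holds 2 libraries of 1 group and 1 of the other, so part of the real difference stays in them. The list's median was −0.269 for the real split and between −0.137 and 0.091 for the others, each time lower on the side with 2 shPostn libraries. They cannot tell whether the preset call is particular to the real groups. With an estimated correlation the unadjusted p was 0.00363 for the real split against 0.206 or more for the others. A difference between the lines that has nothing to do with periostin, such as a clone that took over, cannot be excluded by this design.

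The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. For the changed genes 1 split of 10, the real one, gave as many as 1300, and the highest of the others was 0, with 121 to 847 genes at an unadjusted p under 0.05 against 3458. For the lists 10 of 10 splits gave as many as the real 12, and the highest of the others was 22. The count of 12 lists with the preset correlation is thus no larger than other splits give. What the calls of those splits read was not tested, and each of them keeps part of the real group difference.

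No stem of gene names was enriched among the changed genes: of 399 families the lowest p was that of Cdkn, with 4 of 7 called (Fisher's exact p = 0.00329, adjusted p = 1). Of haemoglobin genes Hbb-bs measured 11.6 CPM in shPostn replicate 3 and 0.0505 to 3.89 CPM in the others.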
